A study of Leucaena leucocephala with 8 samples.

How the data were processed

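Transcript levels were measured in roots and shoots of Leucaena leucocephala, a leguminous tree, with a 1-colour Agilent microarray made for this species. Per the labels, seedlings were grown for 4 weeks at 25 degrees C with 16 h of light and 8 h of darkness, and the drought treatment was 48 h of watering with nutrient solution that held 15% PEG6000, a polymer that lowers the water potential around the roots. Untreated seedlings were collected at the same time. Each of the 4 groups (control root, control shoot, treated root, treated shoot) had 2 biological replicates, each a pool of about 10 seedlings according to the design text, which gives 8 arrays. The tissue field of the labels contradicted the titles, sources and descriptions for the control shoot and treated root samples, where it followed the treatment. Groups were taken from the titles, and on 8 of 8 arrays the closest other array was the replicate given by the titles. Both labellings keep these replicate pairs, so this does not choose between them. Control root correlated with treated root at r = 0.992 to 0.994, but with control shoot at 0.952 to 0.954. Under the tissue field, control root and control shoot would be the same organ under the same treatment, so these values argue against that field. They show which arrays belong together but not which pairs are root and which are shoot. Without gene names the organ of each pair was not checked.

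The authors deposited a scanner file for each array and a value table of the whole series. Per the submitters' processing notes and the file headers, spot intensity was extracted with Agilent Feature Extraction 11.5.1.1. The processed signal in those deposited files is a linear, background-corrected intensity in the Cy3 channel, and no scaling between arrays was found in it. The series table deposited by the authors holds, for 10435 of 10435 transcripts on every array, the mean over a transcript's probes of that same intensity (relative tolerance 1e-06), on the linear scale, not centred and not scaled between arrays. The median of its column ranged from 23.7 in treated shoot replicate 2 to 48.0 in treated root replicate 1, with 39.6 and 32.3 in control root, 27.3 and 26.6 in control shoot, 38.5 in treated root replicate 2 and 35.9 in treated shoot replicate 1. How the transcript sequences were assembled is not given in the sources used here. The files identify transcripts by number and do not pair the numbers with gene names or descriptions. No gene is therefore named, and the tests of drought-related gene lists that had been planned were not run, since no list could be matched to transcripts.

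The array carries 10435 transcripts and 49923 probes, with a median of 5 probes per transcript and 3 to 14 spots per probe. Between 1.58% and 2.02% of spots per array were marked as outliers by the scanner software and left out, and 0 spots were saturated. The log2 of the processed signal was averaged over a probe's spots, and each array's 75th percentile was subtracted, so a level of 0 equals that percentile. A probe was taken as well above background on an array where at least as many of its remaining spots were so as were not. The brightest probe stood for its transcript, and 9117 transcripts that were well above background on at least 2 of the 8 arrays were tested; the other 1318 were not. Arrays give no read depth, and the number of arrays limits the precision: the median standard error of a log2 fold change was 0.13.

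Differences were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package. A mean was fitted for each of the 4 groups over all 8 arrays, with 4 residual degrees of freedom and empirical Bayes moderation (prior SD 0.11 on the log2 scale, 1.83 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method, and the threshold was 0.05. The contrasts were drought in root, drought in shoot, the difference of these effects between the organs, and shoot against root in controls and in treated seedlings. In each contrast, the transcripts with the largest fold change were named among those past the threshold whose arrays did not overlap between groups and that were measured on both arrays of the brighter group. Because no names came with the numbers, at most 2 transcripts per direction are printed. Levels, and the statement that a transcript was not well above background, refer to that brightest probe. Where it was not well above background on any array of a group, its fold change is a bound for that probe, written as at least. Other probes of the transcript can give smaller changes. Where its own levels lay above the floor defined next, the fitted fold is given instead. The bound sets the brighter group's mean against the mean over the dimmer group's arrays. Each of these arrays gives the higher of the transcript's own level and the array's floor, its lowest level of a probe well above background. A probe not well above background can lie above the floor, as transcript 1807590 did in treated root (-5.75, floors -6.75 and -6.63). So at least refers to the floor and is not a strict lower limit. Levels are log2 means with their SD (n = 2 arrays), and fold changes carry their standard errors.

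Each slide held 4 arrays, and all arrays of replicate 1 were on slide 1 and all of replicate 2 on slide 2, so slides were tested as a block and each contrast was also computed within each slide. Each group had the same array position on both slides, so position and group cannot be told apart. Replicates of a group differed by a median of 0.096 to 0.15 on the log2 scale. They were kept as separate samples because the design text calls them biological replicates; the arrays themselves do not show whether the RNA came from separate pools.

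The procedure was tested on simulated data for 9117 transcripts, 200 of them changed, in 20 runs per comparison. In the simulated root comparison it recovered 95.1% of transcripts changed by 2 on the log2 scale, 74.9% of those changed by 1 and 16.1% of those changed by 0.5, and 5.96% of calls were false. In the simulated shoot comparison it recovered 94.6%, 72.7% and 17.3%, and 5.65% of calls were false. The simulated noise was normal and independent, with 1 SD per transcript in all groups and no slide effect. On the arrays, replicate differences correlated between groups at up to 0.398, and their median size was 0.15 in treated shoot and 0.096 in treated root. The simulated rates therefore need not hold for these arrays.

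The tests, the rule for naming transcripts and most alternatives were chosen before the data were examined. The alternatives were quantile normalization, no scaling, scaling on the median, normexp background correction (offset 50), no filter or a stricter filter on dim probes, outlier spots kept, the slide as a block, only the 4 arrays compared, another variance model, every probe tested, the series table's values, a 2-fold minimum and leaving out each array in turn. Normexp used the median signal because the scanner files do not hold the mean signal, and its offset, added to every signal, compresses the fold changes of dim transcripts. Scaling on 5 of Agilent's spike-in probes, those with a median signal between 100 and 100000 on every array, was added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.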

Results

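Transcript levels in roots and shoots of Leucaena leucocephala seedlings were compared after 48 h with 15% PEG6000 and without it, to find transcripts that respond to drought in either organ. The 4 groups had 2 arrays each, and each array held RNA from a pool of about 10 seedlings. The 75th percentile of the processed signal was 359.1 and 289.4 in control root replicates 1 and 2, 285.5 and 252.6 in control shoot, 428.6 and 353.5 in treated root, and 356.2 and 271.9 in treated shoot. Between 61.2% of spots in treated shoot replicate 2 and 70.9% in treated root replicate 1 were well above background. On both arrays of a group, 8470 transcripts were well above background in control root, 8186 in control shoot, 8791 in treated root and 8032 in treated shoot. Replicates correlated with r of 0.993 to 0.997 across transcripts, arrays of the same organ under the other treatment with 0.982 to 0.994, and arrays of different organs with 0.952 to 0.964.

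The first comparison asked which transcripts changed with drought in root. Transcript 1604542 rose from -6.93 ± 0.33 in control root, where it was not well above background, to -2.17 ± 0.06 in treated root (log2 levels, mean ± SD, n = 2), which is at least 16.9-fold (limma adjusted p = 0.000207). All 5 of its probes rose, by 2.14 to 4.76 on the log2 scale, and another of them was well above background on 1 control root array. Transcript 1661768 rose 18.9-fold, from -1.59 ± 0.08 to 2.65 ± 0.04 (log2 fold change 4.24 ± 0.08, SE; adjusted p = 4.09e-05). Both were also higher in shoot than in root in control seedlings. Transcript 1666095, with only 1 tested probe, fell at least 7.82-fold, from -3.45 ± 0.46 to a level not well above background (adjusted p = 0.0212). Transcript 1807590 fell 7.78-fold from -2.79 ± 0.09 (log2 fold change -2.96 ± 0.27, SE; adjusted p = 0.00606), also to a level not well above background. Its signal lay above the floor, so this is the fitted fold and not a bound. The probes of 1807590 differed in size, from -4.07 to -1.79 over 9 tested, and others of them were well above background in treated root. With normexp, the log2 fold changes of these transcripts were 1.08 for 1604542, 3.61 for 1661768, -0.67 for 1666095 and -0.80 for 1807590.

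In root, 483 of 9117 transcripts passed the threshold (5.30%), of which 244 rose and 239 fell. The median log2 fold change was 0.67 among those that rose and -0.59 among those that fell. A change of 2-fold or more was fitted for 54 rising and 30 falling transcripts, and 20 rising and 4 falling transcripts changed 4-fold or more. Of the 20, 15 were higher in shoot than in root in controls and 2 were lower. Of the 51 transcripts that were 16-fold or more higher in shoot in controls, 31 rose in treated root and 1 fell. The log2 fold changes of the slides correlated with r = 0.698 over all tested transcripts. The number of calls in root depended on the model and the scaling: it was 942 with the slide as a block (414 rose, 528 fell) and 72 with no scaling (64 rose, 8 fell), while scaling on the median gave 174 (118 rose, 56 fell) and scaling on spike-in probes 864 (771 rose, 93 fell). It ranged from 36 to 67 without any 1 of the root arrays and was 278 without either control shoot array. Transcript 1666095 missed the threshold in 7 of 21 alternatives and 1807590 in 4 of 21, with the direction kept in each.

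**Figure D1:**
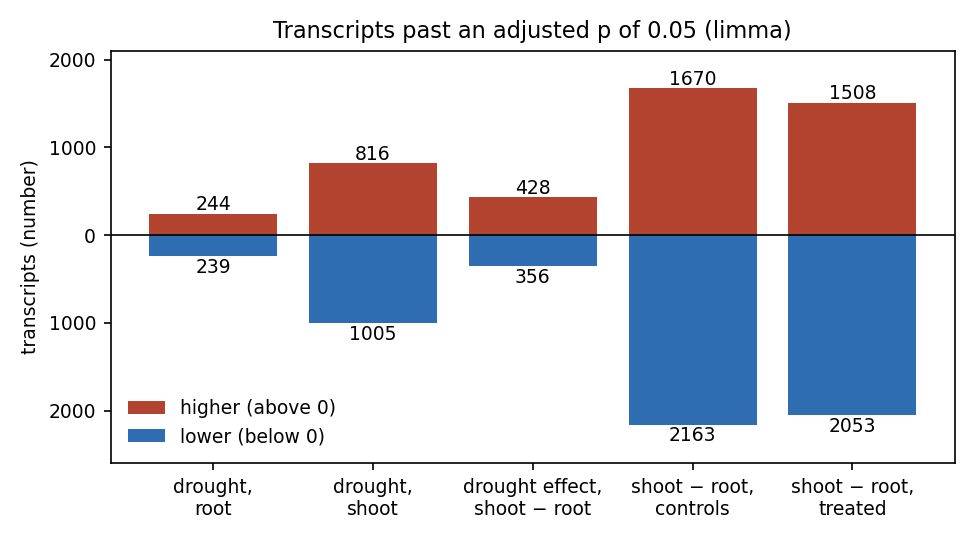
Number of transcripts past an adjusted p of 0.05 in each comparison (limma, 9117 tested), with higher transcripts drawn above 0 and lower ones below. Drought changed 483 transcripts in root and 1821 in shoot, and the organs differed at 3833 transcripts in controls and 3561 in treated seedlings.

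The same question was asked in shoot. Transcript 1805644 was not well above background in control shoot (-6.94 ± 0.44) and reached 0.58 ± 0.12 in treated shoot, a rise of at least 105-fold (adjusted p = 5.57e-05). All 7 of its probes rose, by 2.54 to 7.51 on the log2 scale, and others of them were well above background in control shoot. Transcript 1673302, with only 1 tested probe, rose at least 60.2-fold, from -7.23 ± 0.001 to -0.23 ± 0.09 (adjusted p = 3.54e-06). In root, these transcripts stood at similar levels in both conditions: 1805644 at 0.13 ± 0.04 in control and 0.17 ± 0.03 in treated root, and 1673302 at 0.37 ± 0.10 and 0.50 ± 0.04. Transcript 26122 fell at least 12.5-fold from -2.76 ± 0.12 to a level not well above background (adjusted p = 0.000117), and transcript 1593058 fell at least 8.73-fold from -3.28 ± 0.07 (adjusted p = 0.000315). All 4 kept their call in each of the 21 alternatives that tested them. The stricter filter, well above background on all 8 arrays, left all 4 out, and the 2-fold minimum reuses the main fit, so it could not change their calls. Their sizes did not hold with normexp, which gave log2 fold changes of 2.99 for 1805644, 2.29 for 1673302, -0.88 for 26122 and -0.71 for 1593058. The series table gave 4.93 for 1805644 and -2.98 for 26122.

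In shoot, 1821 transcripts passed the threshold, of which 816 rose and 1005 fell. The median log2 fold change was 0.61 among rising and -0.60 among falling transcripts. A change of 2-fold or more was fitted for 163 rising and 144 falling transcripts, and of 16-fold or more for 12 rising and 1 falling transcript. Of these 12, 9 were not well above background on either control shoot array; with the floor in place of such levels, 10 of the 12 still rose 16-fold or more. All 12 were higher in root than in shoot in controls, with a median log2 difference, shoot minus root, of -5.20 with the floor and -5.73 as fitted. In treated root, 2 of these 12 rose, 3 fell and 7 did not pass the threshold. Of the 39 transcripts that were 16-fold or more higher in root in controls, 18 rose and 4 fell in treated shoot. The log2 fold changes of the slides correlated with r = 0.602 over all tested transcripts. The count was 324 with no scaling (261 rose, 63 fell), 319 when the fit held only the 4 shoot arrays, and 1688 with spike-in scaling (1279 rose, 409 fell). It was 1000 and 717 without control shoot replicate 1 or 2, 1100 without either treated root array, and 1038 without treated shoot replicate 2, the array with the lowest share of spots above background.

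Whether drought acted differently on the organs was tested as the difference between the effects, shoot minus root. Transcript 1549869 had a fitted difference of 8.50 ± 0.64 on the log2 scale (adjusted p = 0.00186): it stood at -5.46 ± 1.08 in control shoot, where it was well above background on 1 of 2 arrays, and at 0.90 ± 0.07 in treated shoot, against 1.55 ± 0.08 in control and -0.59 ± 0.05 in treated root. The difference for transcript 1579183 was 7.59 ± 0.30 (adjusted p = 0.000269). Its control shoot level was not well above background, so the size rests on a signal at the floor, and 1 of its 3 tested probes had that sign. With normexp the difference of 1579183 was 3.11, and the series table gave 3.90. Normexp moved the difference of 1549869 by -3.51, and leaving out control shoot replicate 1 or 2 gave 9.27 and 7.74. Transcript 1661768 had the difference -4.65 ± 0.11 (adjusted p = 8.97e-05), since it rose in root and fell by 0.41 ± 0.08 in shoot. Transcript 1604542 had -4.00 ± 0.22 (adjusted p = 0.000768), with a rise of 0.76 ± 0.15 in shoot. That size also rests on a signal at the floor, in control root, and with normexp the difference was -0.36 and did not pass the threshold (adjusted p = 0.192; range over 20 alternatives 4.97e-06 to 0.192).

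The effects differed for 784 transcripts, 428 with the higher value in shoot and 356 with the higher value in root. Among them, 626 had passed the threshold in shoot, 231 in root and 47 in neither organ. Of the 1545 transcripts called in shoot only, the difference was itself past the threshold for 506, and of the 207 called in root only, for 111. With the slide as a block the count was 1227, and with no scaling it was 107. It ranged from 199 to 289 without any 1 of the root arrays and was 406 and 388 without control shoot replicate 1 or 2.

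Drought calls shared by both organs were counted from comparisons that have no array in common. In the same direction, 191 transcripts changed in both organs. Of these, 95 rose in both, against 21.8 for independent lists, and 96 fell in both, against 26.3. A further 42 rose in root and fell in shoot, against 26.9, and 43 fell in root and rose in shoot, against 21.4. All 4 counts lay above those of independent lists, but the fit gives each transcript the same error in both organs, so part of the excess can come from transcripts with a small error. Among the 276 called in both organs, which direction was shared does not depend on that error, and 69.2% changed the same way (Fisher's exact test of direction in root against direction in shoot, 2-sided p = 2.35e-10, over transcripts that are not independent). Separate fits of the 4 arrays of each organ called 24 transcripts in the same direction and 13 in opposite directions, against 2.61 and 2.53 for independent lists, and there the directions were not shown to be related (exact p = 0.0789). The log2 fold changes of the organs correlated with r = 0.154 and rho = 0.224 across the 9117 transcripts, which are not independent replicates, and with r = 0.190 and 0.0811 when each organ was taken from a different slide. The shared count was 413 with the slide as a block and 16 with no scaling, 15 to 22 without any 1 of the root arrays, and 85 and 81 without control shoot replicate 1 or 2.

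**Figure D2:**
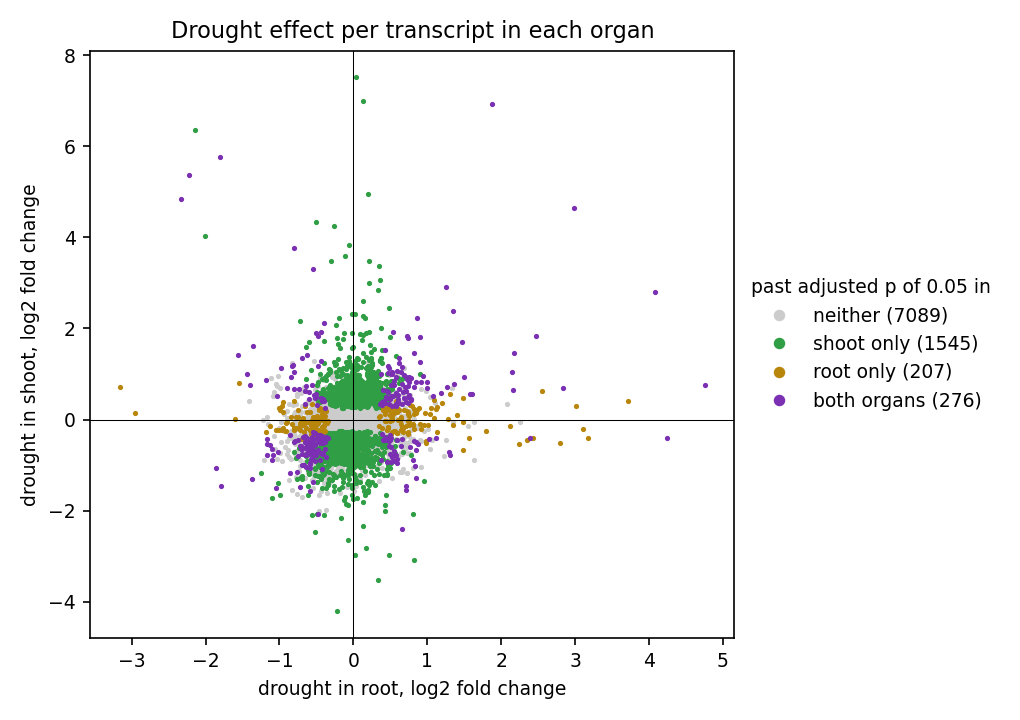
Log2 fold change with drought in root (horizontal) and in shoot (vertical), 1 point per tested transcript, coloured by the organ in which it passed an adjusted p of 0.05. Of the 9117 points, 276 passed in both organs, 85 of them in opposite directions.

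The organs themselves were compared in untreated seedlings. Transcript 1665955 was at least 138-fold higher in shoot (0.86 ± 0.04) than in root, where it was not well above background (adjusted p = 4.46e-06), and transcript 1604542 at least 127-fold higher in shoot (0.74 ± 0.03; adjusted p = 2.02e-06). Transcript 1808320 was at least 636-fold higher in root, at 3.33 ± 0.01, and not well above background in shoot (adjusted p = 2.23e-05). Transcript 1661342 was 327-fold higher in root, at 3.14 ± 0.02 against -5.21 ± 0.35 in shoot, where it was well above background on 1 of 2 arrays (adjusted p = 2.02e-06). With normexp the log2 differences were 3.26, 3.33, -5.45 and -5.22 for these transcripts in turn, against fitted values of 7.70, 7.67, -9.91 and -8.35. Over their tested probes the log2 differences ran from 6.47 to 7.70 for 1665955 and from 4.48 to 7.67 for 1604542. They ran from -10.7 to -8.09 for 1808320 and from -9.12 to -8.35 for 1661342. The folds written as at least therefore refer to the brightest probe, set against the floor, and not to every probe. In all, 3833 transcripts differed (42.0%), of which 1670 were higher in shoot and 2163 in root. The scaling moved this split to 2099 higher in shoot and 1265 in root when scaled on the median, to 662 and 1935 with no scaling, and to 1318 and 2747 with spike-in scaling.

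In treated seedlings, transcript 1667759 was 83.1-fold higher in shoot (1.03 ± 0.14) than in root (-5.34 ± 0.04; adjusted p = 6.11e-06), and transcript 1659299 was 61.7-fold higher in shoot (1.44 ± 0.13 against -4.51 ± 0.04; adjusted p = 2.78e-06). Transcript 1808320 was again not well above background in shoot and at least 748-fold higher in root (3.15 ± 0.07; adjusted p = 2.91e-05). Transcript 1808321 was 218-fold higher in root (3.62 ± 0.06 against -4.15 ± 0.05; adjusted p = 2.78e-06). With normexp the log2 differences were 3.45, 3.78, -5.44 and -5.82 in turn, against fitted values of 6.38, 5.95, -9.60 and -7.77. Over their tested probes they ran from 6.38 to 7.45 for 1667759, from 4.87 to 6.48 for 1659299, from -10.7 to -8.29 for 1808320 and from -9.98 to -7.77 for 1808321. In all, 3561 transcripts differed (39.1%), 1508 higher in shoot and 2053 higher in root, with 2097 and 1070 when scaled on the median, 505 and 2293 with no scaling, and 1098 and 3083 with spike-in scaling. The count was 2142 and 2132 without treated root replicate 1 or 2. Of the transcripts called in controls, 2522 were called in the same direction in treated seedlings and 97 in the opposite direction. Of the 39 transcripts that were 16-fold or more higher in root in controls, 20 were so in treated seedlings, and of the 51 that were 16-fold or more higher in shoot, 25 were. In treated seedlings 36 transcripts in all were 16-fold or more higher in root and 30 higher in shoot, and a set chosen by a limit in controls loses members on any new measurement.

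**Figure D3:**
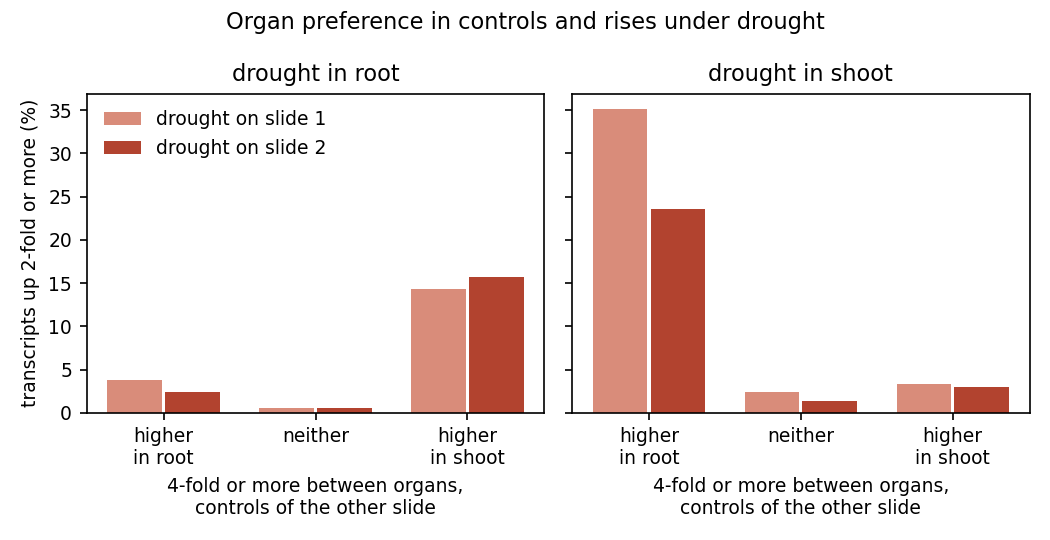
Share of transcripts (%) with a rise of 2-fold or more under drought in root (left) and in shoot (right), taken as 1 treated array against 1 control array of the same slide. Transcripts are grouped by a difference of 4-fold or more between the organs in the controls of the other slide, with 1 bar per slide on which drought was measured. Transcripts higher in root rose in shoot in 35.2% and 23.6% of cases on slides 1 and 2, against 2.36% and 1.42% of those without such a difference. The classes were not matched on level.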

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

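Among the tests below, those on control arrays shared between comparisons, on scaling and on leaving out an array were chosen after the results had been seen. Results drew attention because the drought effect differed between the organs in a test of that difference. This held for 784 transcripts in all, and for the named transcripts 1549869 (8.50, shoot minus root on the log2 scale), 1579183 (7.59), 1661768 (-4.65) and 1604542 (-4.00). The sizes for 1579183 and 1604542 rest on a group at the floor, and that for 1549869 on a control shoot level well above background on 1 of 2 arrays. Only 1 of 3 probes of 1579183 had that sign, and with normexp the difference of 1604542 was -0.36 and missed the threshold.

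The 12 transcripts with a fitted rise of 16-fold or more in treated shoot were all higher in root than in shoot in controls, also with the floor in place of control shoot levels not well above background. Root tissue made up as in the root samples would bring every root transcript into treated shoot. The risers would need a median share of 66.2% root RNA, while the 39 root-preferential transcripts as a set allowed a median of 1.40% (quartiles -0.0900% and 33.6%, with 10 risers among them). RNA from only a part of the root is not covered by this measure. The lowest share any riser needed was 16.3%, and 27 of the 39 stayed below it. Of the 12, 7 stood higher in treated shoot than in treated root, and 4 stood higher in treated shoot than in control root. Chance values of the shared control shoot arrays were argued against by comparing slides with no array in common. There, root-preferential transcripts rose 2-fold at least 14.9 times as often as transcripts without a preference. The classes were not matched on level, so noise of dim transcripts can add to that ratio. Within the root-preferential class, 35.2% and 23.6% rose 2-fold on slides 1 and 2, while 5.49% and 6.25% fell. A single odd probe was argued against by a second rising probe in 6 of the 7 risers that have several tested probes. The remaining risers have no second tested probe, so this does not cover them. A response of these transcripts to drought in shoot is a hypothesis, found and tested on the same arrays. Array position, which was the same for each group on both slides, remains open.

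The mirror pattern in root was less settled: of the 20 transcripts that rose 4-fold or more in treated root, 15 were higher in shoot in controls. The limit was 4-fold here and 16-fold in shoot, and a smaller rise needs a smaller share of the other organ's RNA. The unlike limits can therefore account for part of the contrast with shoot. Shared control root arrays were argued against in the same way, with a ratio of at least 25.9 between classes again not matched on level. On slides 1 and 2, 14.3% and 15.7% of shoot-preferential transcripts rose 2-fold in root, while 3.69% and 2.54% fell. For the 20 risers as a set, shoot RNA in the treated root samples cannot be told apart from a drought response. The 51 shoot-preferential transcripts allowed a median share of 1.78% (quartiles 0.759% and 4.13%), where the 20 risers needed a median of 9.24% (from 1.51% to 720%). That gap is too small for the measure set in advance to decide. Of the 20, 7 stood higher in treated root than in treated shoot, which shoot RNA does not give, but only 2 of these 7 were among the 15. A response to drought in root stays among the open explanations.

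Drought changed more transcripts in shoot (1821) than in root (483). Scaling as the whole cause was argued against by a ratio of at least 1.95 under the other scalings, the lowest with spike-in probes, and a single array by a ratio of at least 2.22, the lowest without treated shoot replicate 2. Shoot replicates differed more than root replicates, which pooled errors could turn into calls. But the SD of the effect shared by both slides was 0.39 in shoot and 0.28 in root on the log2 scale. Noise independent between the slides does not enter this SD, while variation shared by both arrays of a group does. The difference was 0.12 ± 0.01 (SE over 1000 resamples of 7709 transcripts, which are not independent). That SE does not measure variation between seedling pools. A stronger response of shoot than of root is a hypothesis, and array position and a single odd array remain open.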

How the results depend on the processing

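Spike-in scaling was chosen after seeing the data; the other alternatives were planned. No named transcript changed direction. But the balance of rising and falling calls turned with the scaling in shoot and between organs, as given with each comparison. In root, the share of rising calls moved from 50.5% to 89.2% with spike-in probes, 88.9% with no scaling and 67.8% when scaled on the median. Of the named transcripts, 1666095 and 1807590 lost their call in root without either control root or either treated root replicate; 1666095 also did without either control shoot replicate and with only the 4 root arrays, and the difference for 1604542 did with normexp. The others kept theirs, but normexp, whose offset compresses dim signals, shrank most sizes, as 4.76 to 1.08 for 1604542 in root. Quantile normalization, normexp, outlier spots kept and both other filters on dim probes left all counts within 1.5 times. Other counts follow as root, shoot, difference and shared calls, against 483, 1821, 784 and 191. They were 72, 324, 107 and 16 with no scaling. Scaling on the median gave 174 in root, 405 for the difference and 55 shared, and spike-in probes gave 864 in root and 345 shared. The variance model with trend and robust gave 949 in root, 1251 for the difference and 395 shared, the values of the series table gave 890, 1181 and 368, and every probe tested 1010, 3246, 1727 and 484. Fits on only the 4 arrays compared, with fewer residual degrees of freedom, gave 147, 319 and 24 shared. A 2-fold minimum, stricter by construction, left 84, 307 and 316, with 1396 for organs in controls and 1176 in treated seedlings. Apart from these by construction, the cause was not tested.

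With the replicate block, which is the slide, counts were 942 in root, 1227 for the difference and 413 shared; it moved no other count by over 1.5 times. Replicate differences correlated at 0.185 to 0.398 in 5 of the 6 pairs of groups and at -0.0574 between control and treated shoot. Slide and replicate number are 1 factor here, and the fit without the block was kept as planned. The median log2 fold change of all transcripts moved from -0.08 to 0.20 in root and from -0.12 to 0.09 in shoot with no scaling, and to 0.13 and 0.05 with spike-in probes. Shoot minus root, it moved from -0.10 to -0.37 in controls and from -0.14 to -0.46 in treated seedlings with no scaling, to -0.22 and -0.29 with spike-in probes, and to 0.12 and 0.13 when scaled on the median.

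Leaving out 1 array, with the lone remaining replicate assumed to vary like the other groups, gave 36 to 467 calls in root, 717 to 2296 in shoot, 199 to 950 for the difference, 2767 to 4167 between organs in controls, 2132 to 3926 in treated seedlings and 15 to 175 shared. Root calls numbered 36 to 67 without any 1 of the root arrays and 278 without either control shoot array; shoot calls 1000 and 717 without control shoot replicate 1 or 2, 1100 without either treated root array and 1038 without treated shoot replicate 2. The difference was 199 to 289 without a root array and 406 and 388 without control shoot replicate 1 or 2. Organ calls in treated seedlings were 2142 and 2132 without treated root replicate 1 or 2, and shared calls 15 to 22 without a root array and 85 and 81 without control shoot replicate 1 or 2. Signal limits small changes and dim transcripts, and 1318 transcripts were not tested.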

Other observations

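The response to drought was set against organ preference in cross-slide comparisons that share no array, which were chosen after the data had been seen. The classes of organ preference were not matched on level, so their shares can also reflect differences in level between the classes. Of transcripts 4-fold or more higher in root in the controls of slide 1, 23.6% (49 of 208) rose 2-fold or more in shoot on slide 2, against 1.42% of transcripts with no such preference. With the slides exchanged the shares were 35.2% (64 of 182) and 2.36%. Of transcripts 4-fold or more higher in shoot, 15.7% (37 of 236) and 14.3% (35 of 244) rose 2-fold or more in root, against 0.531% and 0.553%. Falls of 2-fold or more in shoot were seen for 15.3% and 10.7% of shoot-preferential transcripts, against 9.29% and 1.38% of those with no preference. The other directions, on slides 2 and 1 in turn, were mixed. In root, 2.54% and 3.69% of shoot-preferential transcripts fell 2-fold or more, against 0.658% and 0.668%, and 5.29% and 8.24% of root-preferential ones did, while 2.40% and 3.85% of root-preferential ones rose, against 0.531% and 0.553%. In shoot, 6.25% and 5.49% of root-preferential transcripts fell 2-fold or more, against 9.29% and 1.38%, and 2.97% and 3.28% of shoot-preferential ones rose, against 1.42% and 2.36%. The organ difference correlated with drought in shoot at r = -0.168 and -0.347 and with drought in root at 0.190 and 0.181 across transcripts, which are not independent.

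Probes of a transcript did not always move together. Among transcripts with at least 2 probes past the threshold, probes went in opposite directions in 5 of 531 in root, 55 of 1763 in shoot and 195 of 3616 between the organs in controls. On slide 2, 805 of 8666 transcripts without organ preference were at least 2-fold lower in treated shoot, against 120 of 8683 on slide 1, and the median log2 fold change in shoot was -0.18 on slide 2 and -0.03 on slide 1. Relative to the spike-in probes, the 75th percentile stood at 0.20 and 0.14 on the log2 scale in treated root against -0.02 and -0.05 in control root, and at 0.06 and -0.01 in treated shoot against -0.09 and -0.22 in control shoot.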
